A study of Mus musculus with 12 samples.

How the data were processed

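RNA was measured in RAW264.7 cells, a mouse macrophage-like line, on 12 Affymetrix arrays, 1 array per sample. The samples form 4 groups of 3, each kept for 24 h in its medium. They are normal medium (replicates 2, 3 and 4), medium conditioned by SCR PyMT-41C cells (SCR medium; 1, 3 and 4), medium conditioned by JMJD6-knockout PyMT-41C cells (KO medium; 1, 2 and 3), and SCR medium with CSH, which the labels name as a blocker of the annexin A1 receptor (1, 2 and 4). Conditioned medium made up 50% of the culture medium per the labels' protocols. JMJD6 was knocked out in the cells that made the medium, so the level of Jmjd6 in the measured cells checks no label. The labels name no group that received CSH in normal medium and no vehicle group. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

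The deposited values are log2 signals made by the authors with RMA in Affymetrix Expression Console on genome build mm10, per the submitters' processing notes; their versions, the probe filter and any batch step are not given in the sources used here. The table holds 65528 probe sets with 0 control probe sets and 0 missing values. Array medians ran from 5.40 to 5.52 on the log2 scale, and no pair of arrays was a duplicate. The number of arrays limits the precision. RMA sets the arrays on a common scale, which would hide a change of total RNA per cell and compresses the changes of dim genes.

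Gene names came from the platform table, updated through Entrez numbers and synonyms in the RefSeq table of GRCm38.p6, the same assembly as mm10. Of the probe sets, 31023 had 1 gene symbol, 1473 had several and 33032 had no listed gene here; 24506 of 25081 probe sets with an Entrez number had all numbers in the RefSeq table. No gene was named from a probe set with several symbols. Where 440 genes had several probe sets, the one with the highest mean stood for the gene. Of 30468 named genes, 18120 exceeded the median of all probe sets of the array in at least 3 arrays and were tested.

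Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with group as the only term over all 12 arrays and eBayes with an intensity trend, 8 residual degrees of freedom and a median residual SD of 0.096. Benjamini-Hochberg adjusted p below 0.05 over all genes tested counted as changed. Of 40 gene lists fixed before the data were examined, 38 had at least 5 tested members. They were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 38 lists of a comparison. Camera and fry used the same intensity trend as the gene tests. They were first run without it, against the design set beforehand, and were rerun with it after those values had been seen; the values without it are among the alternatives.

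For the comparisons of KO medium and of CSH with SCR medium, which share their control arrays, the covariance of the fold changes was set beside 200 simulations of unchanged groups, made from resampled deviations of whole arrays. These were drawn with replacement and with random signs, so 1 array could enter several simulated groups, which the real design does not allow. The return toward normal medium held out each SCR array in turn, chose genes from the other SCR arrays against normal medium, and took the median signed difference of the treated group from the array held out. On simulated data with independent errors for 18120 genes, where 200 genes were changed in KO medium against SCR medium, 95 of 100 genes changed by 0.58 on the log2 scale and 100 of 100 changed by 1 were called, with 8 false calls. Errors shared between genes or arrays were not simulated.

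Genes named in the text follow a rule fixed before the data were examined. They are up to 10 rises and 10 falls per main comparison, largest first, among called genes whose arrays did not overlap between the groups, or the 5 genes with the smallest p where fewer than 5 passed. Added to these are up to 4 members with the smallest p of each list described, the 3 largest rises and falls of each further comparison, and 16 genes reported in every group. Predicted genes, Riken clones, microRNAs and small nucleolar RNAs were counted and not named. Fpr1, Fpr2 and Retnla were not named here in the platform table. Alternatives were other filters, quantile normalization or median centring, eBayes without a trend, array weights, the mean of all probe sets of a gene, the replicate number as a block, each array left out, the 6 arrays of a comparison alone, all probe sets one by one, other thresholds, and the other set tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.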

Results

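Gene expression was measured in RAW264.7 cells, a mouse macrophage-like line, after 24 h in normal medium or in 1 of 3 conditioned media, with 3 arrays per group. PyMT-41C cells, the source of the conditioned media, were either SCR cells or JMJD6-knockout cells. The labels pose 3 questions: how RAW264.7 cells differ in SCR medium, whether the knockout in the medium's source alters that, and whether CSH does. Values are RMA signals on the log2 scale, given as mean ± SD with n = 3, and differences as log2 changes with the standard error (SE) of the limma fit. In the principal components of 18120 genes, PC1 held 71.3% of the variance and parted normal medium, at -42.7 to -37.1, from all conditioned media, at 4.7 to 22.2. PC2 held 5.7% and placed KO medium at 6.8 to 9.7 and SCR medium with CSH at -13.4 to -5.2, on either side of SCR medium. On PC3, SCR replicate 3 lay at -15.9 and SCR replicate 1 at 10.7, so the SCR arrays were spread along a direction that did not part the groups.

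**Figure D1:**
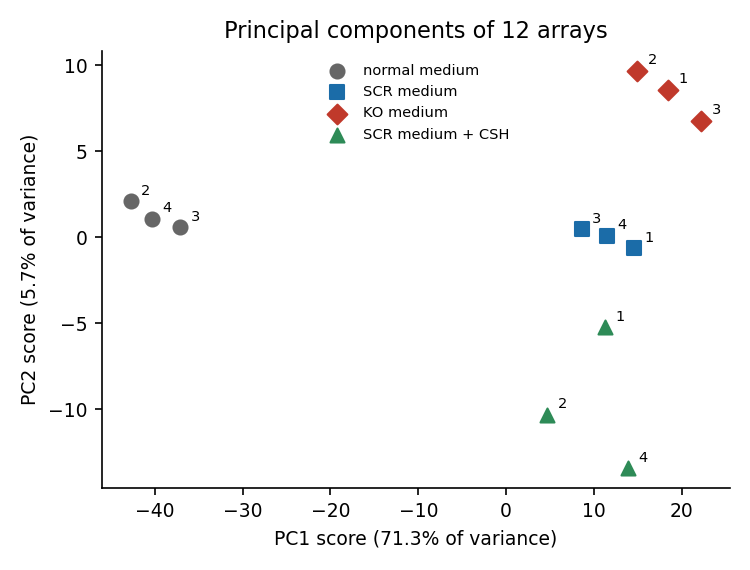
Scores of the 12 arrays on PC1 (71.3% of variance) and PC2 (5.7%) over 18120 genes, with replicate numbers beside the points and 1 symbol per group. Normal medium lies at -42.7 to -37.1 on PC1, and KO medium and SCR medium with CSH lie on opposite sides of SCR medium on PC2.

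Of the comparisons of SCR medium with normal medium and of KO medium and CSH with SCR medium, the first changed the most genes. F5, coagulation factor V, rose from 6.31 ± 0.07 to 10.35 ± 0.21, a log2 change of 4.04 (SE 0.11, adjusted p = 2.3e-10). Plaur, the urokinase receptor (GRCm38.p6, chromosome 7, 24460937 to 24475970), rose by 3.37 (SE 0.13) and Ccr1, a chemokine receptor, by 3.62 (SE 0.17). The other leading rises were Car6 (4.64), Avil (3.71), Sh2d6 (3.14), Qpct (2.84), the neutrophil chemokine gene Cxcl2 (2.81), Slc43a3 (2.79) and Bglap2 (2.74). Ephx1, microsomal epoxide hydrolase (chromosome 1, 180989556 to 181017569), fell from 13.01 ± 0.19 to 9.47 ± 0.08, a change of -3.53 (SE 0.11). Falls were also led by Yipf7 (-3.32), Olfr110 (-3.04), Cd72 (-3.01), Olfr111 (-2.97), Ankdd1a (-2.94), Rasgrp3 (-2.49), Cybb, a subunit of the phagocyte NADPH oxidase (-2.47), Cx3cr1, the fractalkine receptor (-2.39), and Fabp4 (-2.37). In all, 6370 of 18120 genes changed, 3504 up and 2866 down, of which 257 and 300 moved at least 2-fold. The 3 arrays of one medium all lay above those of the other for 43.3% of genes, where chance gives 10%. With a fold of at least 1.5 added to the threshold, 1676 genes changed.

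Genes of mitosis fell together in SCR medium. Of 42 tested, 39 fell, 1 rose and 2 did not pass, with a median of -1.34; adjusted over the list alone, 41 fell and 1 rose. Examples were Cenpf (-2.10), Kif23 (-2.10), Cdc25c (-1.68) and Dlgap5 (-1.50), which act in chromosome segregation, cytokinesis or entry into mitosis. The list passed camera (adjusted p = 9.78e-23) but not with an estimated correlation (adjusted p = 0.564). Of 40 genes of DNA replication, 17 were lower and 5 higher, 19 and 5 adjusted over the list alone, with a median of -0.18. They included Tk1 (-0.97), E2f8 (-0.91), Uhrf1 (-0.57) and Clspn (-0.50), with camera adjusted p = 0.00203 and adjusted p = 0.835 with an estimated correlation.

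Most tested targets of ATF4 and most tested genes of the unfolded protein and NRF2 lists rose in SCR medium. These lists passed camera but not with an estimated correlation. The heat shock list did not pass camera (4 of 11 higher and 2 lower, 5 and 3 adjusted over the list alone, camera adjusted p = 0.59). Of 37 targets of the amino acid response factor ATF4, 29 rose and 1 fell, the same numbers as adjusted over the list alone, with a median of 0.60. Among them were Aldh1l2 (2.61), Ppp1r15a (2.17), the tryptophan tRNA synthetase gene Wars (1.82) and the cystine transporter gene Slc7a11 (1.36). The camera adjusted p was 5.24e-12 and, with an estimated correlation, adjusted p = 0.564. In the unfolded protein response list, 13 of 21 rose and 1 fell (14 and 2 adjusted over the list alone), led by the chaperone gene Hspa5 (1.58), Selenos (1.15), Dnajb9 (1.10) and Sel1l (0.72). In the NRF2 list, 11 of 19 rose and 2 fell (13 and 3 adjusted over the list alone), with Sqstm1 (1.68), Me1 (1.27) and the ferritin light chain gene Ftl1 (0.50). Their camera adjusted p-values were 0.000214 and 0.00671, and with an estimated correlation adjusted p = 0.787 and 0.835.

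In the CREB and cAMP list, 10 of 16 rose and 3 fell, both over all genes and adjusted over the list alone, with Fosl2 (2.02), Vegfa (1.32), Dusp1 (1.23) and Crem (0.91). In the classical activation list, 9 of 19 rose and 2 fell (10 and 2 adjusted over the list alone), led by the high-affinity IgG receptor gene Fcgr1 (2.57), Il1a (2.06), Tlr4 (1.42) and Il23a (1.25). Of 20 cytokine and chemokine genes, 10 were higher and 2 lower (11 and 3 adjusted over the list alone): Cxcl2 (2.81), Cxcl14 (1.89) and Tnfsf9 (1.74) rose while Cxcl16 (-1.61) fell. In the TGF-beta list, 8 of 17 rose and 3 fell (9 and 3 adjusted over the list alone), with Tgm2, tissue transglutaminase (2.38), Skil (1.27), Tgif1 (1.02) and Ski (0.61). Of 10 dendritic cell markers, 5 fell and 0 rose, also adjusted over the list alone, among them Itgax (-1.27), Bst2 (-0.87), Cd83 (-0.71) and Irf8 (-0.46). The Cd83 value comes from a probe set of unmapped sequence, and its other, dimmer probe set gave -0.26. These 5 lists had camera adjusted p-values from 0.00671 to 0.0427, and with an estimated correlation adjusted p = 0.564 to 0.787. With 1 array left out, calls were lost by the TGF-beta list (adjusted p from 0.0156 to 0.0844; without normal replicate 3, SCR replicate 3 or 4, or CSH replicate 2), the dendritic cell list (up to 0.0674, without SCR replicate 1) and the cytokine list (up to 0.10, without SCR replicate 3). The alternative activation list did not pass (camera adjusted p = 0.144, median 0.12), although Il4ra (2.27) and Tgm2 rose and Trem2 (-1.24) fell. Of 38 lists, 10 changed; none did with an estimated correlation, 16 did by fry, and 6 did under a stricter filter on low values.

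Genes reported in every group showed the following. Anxa1, annexin A1, fell from 11.42 ± 0.08 in normal medium to 10.63 ± 0.07 in SCR medium (adjusted p = 2.67e-06), and stood at 10.48 ± 0.05 in KO medium and 10.54 ± 0.11 with CSH. Arg1, arginase 1 (chromosome 10, 24915207 to 24927470), read 6.03 ± 0.11, 6.91 ± 0.26, 8.0 ± 0.19 and 6.61 ± 0.16 in normal, SCR, KO and CSH-treated SCR medium. Vegfa read 12.78 ± 0.09, 14.10 ± 0.13, 14.49 ± 0.01 and 13.91 ± 0.05 in that order. The costimulatory gene Cd86 rose in SCR medium by 1.56 (SE 0.16) and the protease gene Mmp9 by 0.64 (SE 0.09). Il6 rose by 1.04 (SE 0.34, adjusted p = 0.0301) from 4.95 in normal medium, below the array medians of 5.40 to 5.52, so its size there is uncertain, and leaving out single arrays gave adjusted p from 0.00246 to 0.102, with the call lost without normal replicate 2 or 4 or SCR replicate 1 or 3. Tnf (0.42, adjusted p = 0.0672), Nos2 (0.19, adjusted p = 0.402) and Jmjd6 (-0.15, adjusted p = 0.392) did not pass. Mrc1, Chil3, Il10 and Il1b did not pass the filter on low values, with group means no higher than 5.27.

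**Figure D2:**
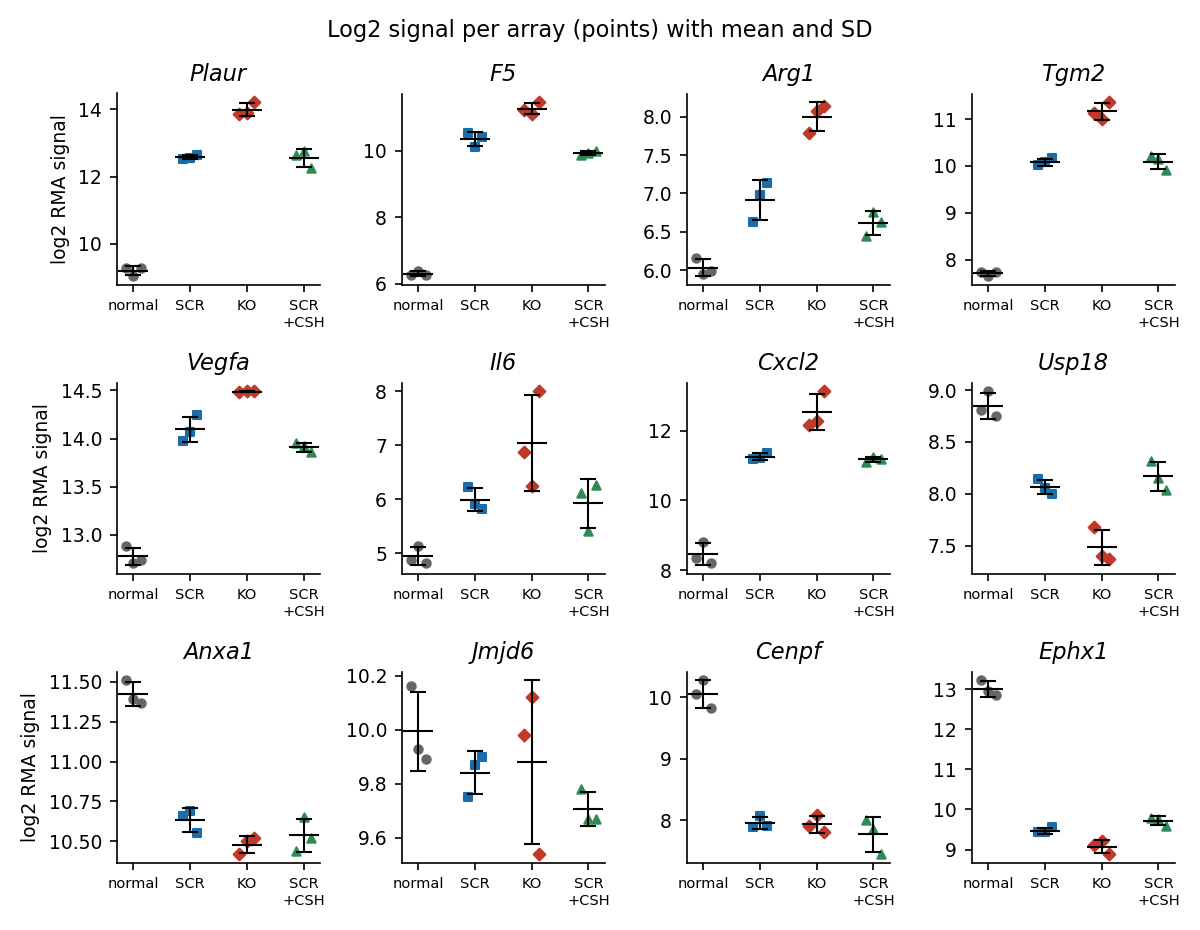
Log2 RMA signal of 12 genes in each of the 4 groups; points are single arrays, and bars give the mean and SD of 3 arrays, on axes that differ between panels and do not start at 0. Arg1 stands at 8.0 in KO medium and 6.91 in SCR medium, while Anxa1 stands at 11.42 in normal medium and at 10.63 or below in the conditioned media.

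KO medium was then set against SCR medium to ask whether JMJD6 in the cells that condition the medium matters to its effect. Plaur rose further, from 12.57 ± 0.06 to 13.99 ± 0.19, a log2 change of 1.42 (SE 0.13, adjusted p = 0.000311). Osbp2, an oxysterol-binding protein gene, rose by 1.39 (SE 0.12), Cxcl2 by 1.28 (SE 0.21), Pdpn, podoplanin, by 1.23 (SE 0.08, adjusted p = 1.37e-05), and Arg1 by 1.09 (SE 0.13). Tgm2 (1.08), Fosl2 (1.05), Pmepa1 (1.02), Scimp (0.92) and F5 (0.91) completed the leading rises. The falls were Cd180 (-0.61), Usp18, an interferon-stimulated gene (-0.58), and Rilpl2 (-0.34). In all 49 genes changed, 46 up and 3 down. Over all tested genes the arrays of the groups did not overlap for 9.4%, where chance gives 10%. Of the 46, 39 were also higher in SCR medium than in normal medium, where independent lists would share 8.9, and 3 were lower. These comparisons share the SCR arrays, whose chance error pushes them in opposite directions. At an unadjusted p below 0.05 there were 1078 genes, against 906 expected by chance. Without any 1 of the SCR or KO arrays 19 to 34 of the 49 calls were kept, the 6 arrays alone gave 22 calls, and array weights gave 379, of which 220 were higher and 159 lower, so the one-sided balance was not kept there. In that fit SCR replicate 4 took a weight of 6.15. Among the named genes, the calls of Cd180, Cxcl2, Fosl2, Scimp, Usp18 and Rilpl2 were lost when some single arrays were left out, with adjusted p reaching 0.168, 0.127, 0.0929, 0.0762, 0.138 and 0.151.

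By gene list, KO medium differed from SCR medium in 12 of 38, 9 up and 3 down; none of the 38 passed with an estimated correlation, and 6 did by fry. In the CREB and cAMP list, 5 of 16 rose over all genes and 11 adjusted over the list alone, with a median of 0.40: Arg1, Fosl2, Crem (0.66) and Dusp1 (0.65). The camera adjusted p was 4.59e-19 and, with an estimated correlation, adjusted p = 0.0847. Among cytokine and chemokine genes, 2 of 20 rose over all genes and 8 adjusted over the list alone, with a median of 0.26. Cxcl2 and the IL-6 family cytokine gene Lif (0.57) passed, and Ccl2 (0.71, adjusted p = 0.0813) and Cxcl14 (0.45, adjusted p = 0.0887) did not. In the alternative activation list, 3 of 20 rose, namely Tgm2, Arg1 and Il4ra (0.62), and in the classical list 1 of 19, Il23a (0.73); adjusted over each list alone, 5 rose in both, and 1 fell in the former. In the TGF-beta list 2 of 17 rose, Tgm2 and Pmepa1, also adjusted over the list alone. With an estimated correlation, adjusted p = 0.0847 for the cytokine, alternative activation and TGF-beta lists and adjusted p = 0.087 for the classical one. In the matrix, protease and angiogenesis list 3 of 19 rose over all genes, and 5 rose and 1 fell adjusted over the list alone: Plaur, Hbegf (0.90) and Vegfa (0.39, adjusted p = 0.0332) rose. Leaving out single arrays gave Vegfa adjusted p from 0.0222 to 0.147, and also ended the calls of Crem (up to 0.0929), Il23a (up to 0.118) and Ddit4 (up to 0.135). Of immediate early genes 2 of 29 rose (9 adjusted over the list alone), Dusp1 and Fosl2, and of ATF4 targets 1 of 37 (4 adjusted over the list alone), Ddit4 (0.61). For these 3 lists the estimated correlation gave adjusted p = 0.204.

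The remaining lists that passed camera between KO and SCR medium held few called genes. The NF-kB list had a median of 0.10 with 0 of 21 members past the test over all genes and 2 higher adjusted over the list alone, namely Nfkbiz (0.29) and Cd83 (0.47, and 0.18 by its other probe set). Interferon-stimulated genes had a median of -0.07, where 1 of 30, Usp18, fell, also adjusted over the list alone. Class I antigen presentation had a median of -0.09 with 0 of 13 past the test over all genes, and 1 higher and 1 lower adjusted over the list alone. DNA replication had a median of -0.04 with 0 of 40 past either test. With an estimated correlation these 4 lists had adjusted p = 0.204, 0.34, 0.658 and 0.967. Single arrays left out ended the calls of the class I list (adjusted p up to 0.513) and of DNA replication (up to 0.226), each without SCR replicate 1 or KO replicate 3, the former also without KO replicate 2 and the latter without SCR replicate 3. The mitosis list, which fell in SCR medium, had a median of 0.05 between KO and SCR medium and did not pass (camera adjusted p = 0.293). Il6 differed by 1.05 (SE 0.34, adjusted p = 0.502), with single KO arrays at 6.25, 6.88 and 8.0. Anxa1 (-0.15, adjusted p = 0.837), Tnf (0.11), Nos2 (0.07), Cd86 (0.08), Mmp9 (0.19) and Jmjd6 (0.04) did not pass.

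**Figure D3:**
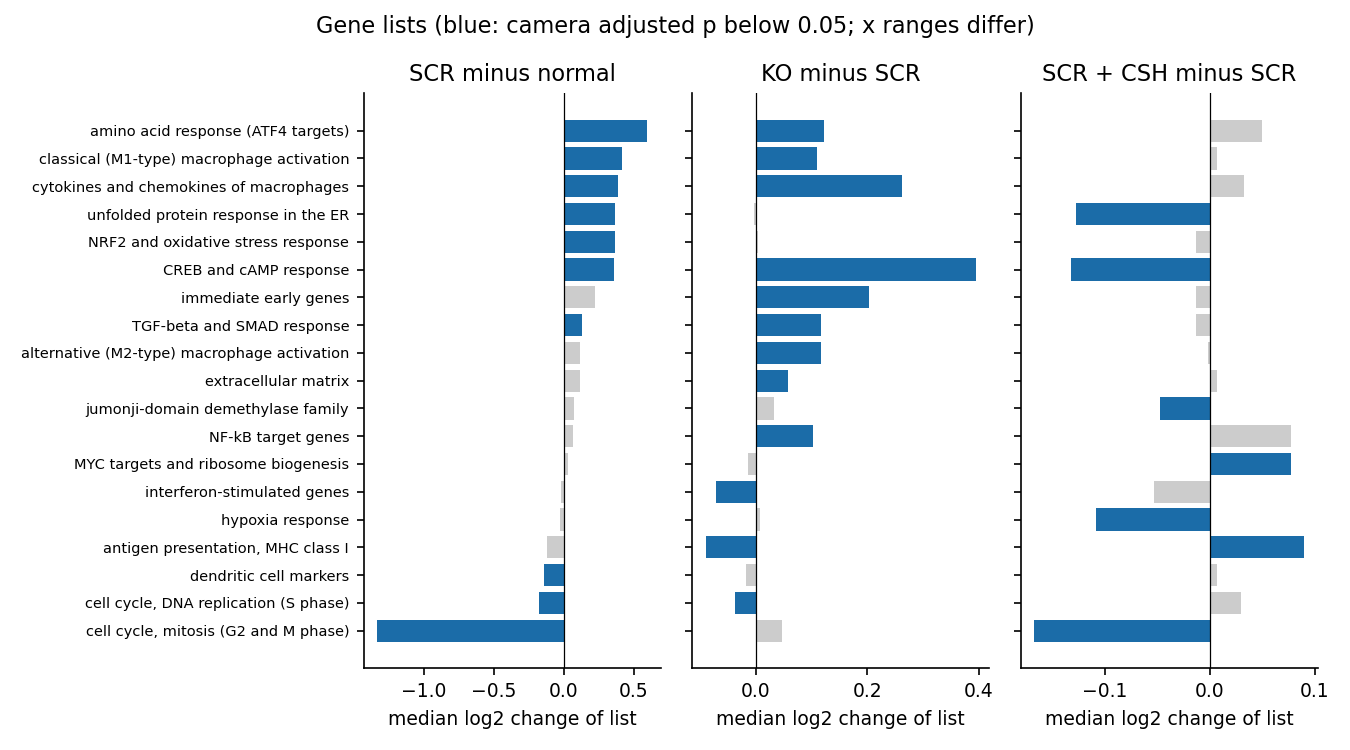
Median log2 change of each gene list that passed camera in at least 1 of the 3 main comparisons, with bars in blue where the adjusted p lay below 0.05 and grey elsewhere; the 3 x axes differ in range. The mitosis list stands at -1.34 for SCR against normal medium and at 0.05 for KO against SCR medium, and the CREB and cAMP list at 0.40 for KO and -0.13 for CSH against SCR medium.

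Adding CSH to SCR medium changed 0 of 18120 genes in the limma test. At an unadjusted p below 0.05 there were 1131 genes against 906 expected, and the smallest adjusted p was 0.0608. The arrays of the groups did not overlap for 8.6% of genes, against 10% by chance. The 5 genes with the smallest p were Cahm (0.42, SE 0.05), Btg1, an antiproliferative gene (-0.74, SE 0.12, adjusted p = 0.206), Rps16-ps3 (0.30), Hacd2 (0.32) and Dhrs9 (-0.32), the last 3 with adjusted p = 0.538. Of the genes reported in every group, Arg1 differed by -0.30 (SE 0.13, adjusted p = 0.781), Vegfa by -0.19 (SE 0.07, adjusted p = 0.76), Tnf by 0.25, Anxa1 by -0.10, Cd86 by -0.11, Mmp9 by -0.09, Il6 by -0.06, Nos2 by -0.03 and Jmjd6 by -0.13. A stricter filter and a random replicate block each gave 1 gene, as did an adjusted p below 0.1, and array weights gave 79. No single array left out gave a call.

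Although no gene passed, 7 of 38 lists passed camera with CSH, all with medians no larger than 0.17 in size and 0 members past either gene-level test. The unfolded protein response list had a median of -0.13, with Hspa5 at -0.36, Calr at -0.37, Dnajc3 at -0.34 and Hsp90b1 at -0.16. Mitosis stood at -0.17, with Nusap1 at -0.39, Kif4 at -0.33, Anln at -0.26 and Mad2l1 at -0.21, and over single arrays left out its median ran from -0.29 to 0.008 and its adjusted p from 3.46e-15 to 0.818, the last without CSH replicate 4. The hypoxia list had a median of -0.11, with Ero1a at -0.28, Egln1 at -0.22 and Ndrg1 at -0.21, and the CREB and cAMP list one of -0.13, with Per2 at -0.18 and Dusp1 at -0.18. The jumonji-domain list had a median of -0.05, with Jmjd1c at -0.15. Upward medians came from MYC targets (0.08), with Nop2 at 0.29, Pa2g4 at 0.23, Srm at 0.22 and Noc4l at 0.19, and from class I antigen presentation (0.09), with H2-M3 at 0.19. With an estimated correlation each of these 7 lists had adjusted p = 0.908, and fry called 0. Leaving out single arrays ended the mitosis call (also without SCR replicate 3) and those of the hypoxia (without SCR replicate 4), MYC target (without SCR replicate 3), jumonji-domain (without SCR replicate 1 or 4 or CSH replicate 2 or 4) and class I lists (without SCR replicate 3 or 4 or CSH replicate 1 or 4), with adjusted p reaching 0.0923, 0.189, 0.161 and 0.265 for the last 4.

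The other media against normal medium were tested in the same way. In KO medium F5 rose by 4.95 (SE 0.11), Car6 by 4.80 and Plaur by 4.78, and Ephx1 (-3.94), Olfr110 (-3.69) and Olfr111 (-3.62) fell most. With CSH, Car6 rose by 4.45, F5 by 3.62 and Ccr1 by 3.50, and Ephx1 (-3.29), Yipf7 (-3.07) and Ankdd1a (-2.98) fell most. KO medium changed 7080 genes against normal medium, 3886 up and 3194 down, and SCR medium with CSH changed 6494, 3787 up and 2707 down. With a fold of at least 1.5 the counts were 2077 for KO medium and 1628 for CSH. Without that fold, rises made up 54.9% of the changed genes for KO medium and 58.3% for CSH. After median centring these shares were 54.3% and 54.7%, so the larger share of rises with CSH depended on the scale of the arrays. A single test across the 4 groups called 6531 genes.

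KO medium and SCR medium with CSH differed from each other in 345 genes, 219 higher and 126 lower in KO medium. Osbp2 (1.65), Plaur (1.44) and Arg1 (1.39) were the largest rises, and Itgax (-1.13), Hpse, heparanase (-0.96), and Fads2, a fatty acid desaturase (-0.87), the largest falls; the calls of Itgax and Fads2 were lost without some single arrays, at adjusted p up to 0.0758 and 0.0735. Vegfa was higher by 0.58 (SE 0.07, adjusted p = 0.00104). The count was 124, 157 and 153 without KO replicates 1, 2 and 3 and 201 without CSH replicate 4, and it ran from 107 without CSH replicate 2 to 373 without SCR replicate 3. It was 574 after quantile normalization and 602 after median centring, where 67.4% and 70.9% of calls were higher against 63.5% here. The share was 56.4% of 653 with array weights, 54.9% of 528 over all probe sets and 87.5% of 80 at adjusted p below 0.01. Without single arrays it ran from 56.2% (CSH replicate 4) to 76.6% (CSH replicate 2).

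The KO and CSH effects against SCR medium were compared over all genes tested. Their covariance was 0.00014, inside the range of -0.00108 to 0.012 simulated for unchanged groups that share the SCR arrays. The correlation across genes, which are not independent replicates, was 0.0124. Its simulated mean was 0.469 and its simulated range -0.177 to 0.866. In the simulation 1 array could enter several groups, which can widen these ranges. Shared arrays raise the covariance without any effect, so whether the effects vary together stays undecided. With 0 calls for CSH no overlap of calls could arise, and 3 control arrays are too few to split into parts of 2. For the genes that SCR medium changed, KO medium lay further from normal medium than the SCR array held out by a median of 0.033, 0.10 and 0.063 in the 3 rounds, with a mean of 0.066, over 5128 to 6164 genes. The KO medians had an SD of 0.033, and their mean was 0.043 without SCR replicate 3 and 0.09 without SCR replicate 1. SCR medium with CSH gave medians of -0.043, 0.030 and -0.013 with a mean of -0.0089, less than their SD of 0.037. That mean changed sign with single arrays left out, at -0.035 without SCR replicate 3 and 0.005 without SCR replicate 4.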

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

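The tests of tumour-cell markers below were chosen after the result they bear on was seen, and the reading of the covariance was changed after its value was seen; the other tests in this part were stated before. KO medium and SCR medium with CSH, both set against SCR medium, differed from each other in 345 genes by a direct test. Outside the named genes, 2058 of 15727 probe sets without a single gene name changed between SCR and normal medium, 766 up and 1292 down, 3 changed between KO and SCR medium and 0 with CSH. With groups of 3, no array was tested as an outlier.

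The genes changed by KO medium mostly moved further along the response to conditioned medium. A common factor for the whole response was set at its median of 1.10 over 557 genes, with quartiles of 1.04 and 1.18. From it 16 genes departed, all higher and all among the 49 calls, which argues against 1 factor shared by all genes. A more strongly conditioned medium need not move every gene by 1 shared factor, so this test cannot decide on it and it stays open. The mean held-out median stayed at 0.043 (SD 0.024) without SCR replicate 3 and at 0.053 (SD 0.021) after quantile normalization. Both stayed above 0 by more than their SD. That was the outcome set beforehand against that array as the sole source and against scale differences left between the deposited arrays. Those SDs rest on 2 and 3 medians and leave out the spread of the KO arrays, which were the same in every round. Without SCR replicate 3, each round chose genes from 1 SCR array. RMA had already set the arrays on a common scale before the second test. Neither value shows that the shift exceeds the noise between arrays, so neither can decide on these 2 explanations. A difference in what JMJD6-knockout cells release may underlie the pattern as a hypothesis, but the number of independently conditioned media is not given, so the batch of medium stays open.

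A further pattern is the width of the response to conditioned media itself. Tumour-cell RNA carried over would raise epithelial markers, whose median change over 37 genes was 0.010 (SD 0.196), under the 0.1 set against carry-over but within that SD of the 0.2 set for it; 11 of the 37 passed the filter, Csn3, a milk protein gene, was higher by 0.51 and St14 was lower (-1.02). The 300 falls of at least 2-fold would need as much tumour RNA as macrophage RNA and a marker rise of 1 or more. In SCR medium the median was 0.013 (SD 0.201), with Krt8, near the array medians, at 5.48 in normal and 5.54 in SCR medium. By limma, Csn3 was a called rise there (0.46, adjusted p = 0.00135) and St14 a called fall (-1.06, adjusted p = 1.01e-06). The median argues against carry-over for those falls of at least 2-fold only if the source cells express these markers, which no array here measured. Carry-over stays open for rises and smaller changes. After quantile normalization 6811 genes changed, which argues against scale differences left between the deposited arrays as the source of this width. Some differences remained, since this step moved the count for KO medium against CSH from 345 to 574. RMA had already set the arrays on a common scale, with medians of 5.40 to 5.52, so the step could hardly lower the count for SCR against normal medium. It cannot decide on a distortion from that common scale itself. Secreted factors, spent nutrients and the dilution of fresh medium may each contribute and were not tested apart.

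KO medium and CSH appear on opposite sides of SCR medium in the principal components. Over all genes an opposite movement was not shown: the observed covariance of 0.00014 is not negative and lies inside the range simulated for noise of shared arrays, -0.00108 to 0.012. Such noise moves both effects the same way (simulated mean 0.00426), so a value between that mean and the lower end is read here as undecided, whereas the reading set beforehand took any value inside the range as noise. The observed minus simulated covariance stayed at or below -0.0018 without any 1 array, which cannot decide between a single array and an effect while the value lies inside that range. The range may be too wide, since 1 array could enter several simulated groups, so lying inside it decides little.

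Other splits of the arrays gave the following. In fits on 6 arrays, the real split gave 5636 genes for SCR, 7044 for KO and 6065 for CSH-treated medium against normal medium, 22 for KO against SCR medium and 162 for KO medium against CSH. The highest other split gave 0 each time, so 1 of the 10 splits reached the real count. For CSH against SCR medium all 10 splits gave 0. With 10 splits no share under 0.05 can arise. For the test across 4 groups, the real split was counted as 1 of 100, and the others were drawn at random. Only the real one reached 6531 genes, the smallest share that 100 splits allow. A random split of these arrays thus seldom gives such a count. Splits that mix normal with conditioned arrays put the large difference between media into the residual spread, so their low counts say little about chance. Since replicates may be technical, the splits do not exclude chance differences between single cultures or batches of medium. The next highest split across 4 groups gave 6261 and was the only other one that kept the 3 normal medium arrays together, and the rest gave at most 1. The count thus reflects mainly that normal medium stands apart, and this test does not show a grouping among the conditioned media.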

How the results depend on the processing

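Of the values of named genes under the alternatives, 5802 stayed on their side of the threshold, 104 lost the call, 42 gained it and 0 reversed. For gene lists 2339 stayed on their side, 81 lost the call, 73 gained it and 6 reversed. A reversal was counted only where the main fit or the alternative made a call. Values uncalled in both may have changed sign. Same-numbered arrays did not all deviate together, so the numbers were not taken as pairs: their correlations ran from -0.065 to 0.295 with a median of 0.069, above 0.1 in 5 of 12 pairs, against a median of -0.047 and 8 of 42 for different numbers. All 3 pairs of replicate 1 lay above 0.1 (0.141, 0.211 and 0.295), and those of replicate 2 stood at 0.075, 0.118 and 0.25. Pairs of replicates 3 and 4 ran from -0.065 to 0.063. Not every array correlated best with one of its own number. With the replicate block the counts were 5860, 39 and 0 for the 3 main comparisons, and 214 for KO medium against CSH (121 higher and 93 lower); of the 49 calls for KO against SCR medium it kept 32, and its 39 were 30 higher and 9 lower. A random block gave 1 gene for CSH. Camera takes no random block, so lists were not run with it; without an intensity trend the lists passing camera stayed at 10, 12 and 7, and no list or named gene lost or gained a call. The cause of a move was not tested unless given. For KO against SCR medium, 49 genes (93.9% higher) became 379 with array weights (58% higher), 22 on the 6 arrays alone, 32 over all probe sets, 19 at adjusted p below 0.01 and 28 with a 1.5-fold threshold. For CSH, 0 became 79 with array weights and 1 with a stricter filter or adjusted p below 0.1. For KO medium against CSH, 345 became 210 with no filter, 574 after quantile normalization, 602 after median centring, 653 with array weights, 162 on 6 arrays, 528 over all probe sets, 80 and 631 at adjusted p below 0.01 and 0.1, and 72 with a 1.5-fold threshold. That threshold left 1676, 2077 and 1628 genes for SCR, KO and CSH-treated medium against normal medium. The array weight estimate stopped before it converged and gave SCR replicate 4 a weight of 6.15 and SCR replicate 3 one of 0.393; what raised its counts was not tested, and its covariance difference was -0.00042 against -0.0041. Lists changed numbered 0, 0 and 0 with an estimated correlation and 16, 6 and 0 by fry for SCR against normal medium, KO and CSH; a stricter filter gave 6 for SCR medium. With each array left out, counts ran from 20 (without SCR replicate 3) to 50 for KO against SCR medium, with 25, 23, 20 and 22 without SCR replicates 1 and 4 and KO replicates 1 and 3, and from 107 to 373 for KO medium against CSH, with 124, 157 and 153 without KO replicates 1, 2 and 3, 107 without CSH replicate 2 and 201 without CSH replicate 4. CSH lists ran from 5 to 11 (without SCR replicate 1). Without a filter, medians counted as reversed included 0.00 for dendritic cell markers (SCR against normal medium). The matrix list (KO against SCR medium) also stood at 0.00 there. With each array left out, KO against SCR medium ran from -0.045 to 0.036 for MYC targets, -0.044 to 0.034 for oxidative phosphorylation and -0.072 to 0.057 for glycolysis, and CSH from -0.294 to 0.008 for mitosis. Signal over background limits genes near the array median.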

Other observations

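Macrophage identity genes moved both ways in SCR medium: of 22 tested, 8 rose and 10 fell against normal medium. Fcgr1 (2.57), Clec4d (1.35) and Cd53 (1.18) rose, and Adgre1, which encodes the F4/80 antigen, fell by 1.45 on the log2 scale. The list as a whole did not pass (camera adjusted p = 0.912). Of 24 hypoxia genes 4 rose and 7 fell, with Vegfa (1.32) and Ero1a (0.96) against Selenbp1 (-2.0) and Car12 (-1.09), and the list did not pass (adjusted p = 0.59). In the annexin and formyl peptide receptor list, Anxa3 (0.56) and Anxa2 (0.21) rose while S100a4 (-1.62) and Anxa1 (-0.79) fell. Fpr1, Fpr2 and Fpr3 of this list were not named in the platform table, so the list gives no level for these receptor genes. The call of Anxa2 was lost without normal medium replicate 4, where adjusted p reached 0.137, and without normal replicate 3 or SCR replicate 1 or 4; over single arrays left out it was 0.0213 or more.

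Metabolic lists did not pass camera between SCR and normal medium, although many members changed. Of 22 genes of fatty acid synthesis and lipid storage 12 fell and 6 rose (adjusted p = 0.144), of 18 cholesterol synthesis genes 8 fell and 3 rose (adjusted p = 0.144), and of 18 glycolysis genes 6 fell and 0 rose (adjusted p = 0.103). Interferon-stimulated genes split, with 8 of 30 higher and 7 lower. Oas3 (-1.76), Bst2 (-0.87) and Usp18 (-0.78) fell and Herc6 (0.57) rose.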
